A study of Mus musculus with 6 samples.

How the data were processed

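Hippocampal RNA from 6 male mice on a C57BL/6J background was sequenced, 1 library per mouse, with 3 mice in each of 2 groups. Per the labels' protocols, RNA was purified on columns and 10.0 ng of total RNA per library went into a strand-specific SMART-Seq kit, a template-switching method for small inputs. Such a kit primes along the whole transcript, so ribosomal RNA that escapes its removal step stays in the library. The labels give every mouse its own number, so the replicates are separate animals.

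Per the submitters' processing notes, reads were converted with bcl2fastq 2.20, trimmed with fastp 0.20.1, and processed with STAR, RSEM and edgeR 3.36.0 on the mouse genome build mm10. The versions of STAR and RSEM, the strand setting and the annotation release were not given in the sources used here. The deposited table holds expected counts per gene, the estimates RSEM makes when it shares reads that fit several genes among them, and between 26.2% and 31.4% of the values in each library were not whole numbers. Genes with near-identical copies, such as the metallothioneins Mt1 and Mt2, the class I antigen-presentation gene H2-K1 and mitochondrial genes with nuclear copies, therefore carry an uncertainty that the counts do not show. The same deposited table gives the authors' log2 fold change and mean log2 CPM of each gene, with a p-value and an adjusted p-value, and the column names are those of edgeR. The table listed 20620 genes, of which 384 had no symbol. In each of them the third highest count over the 6 libraries was at least 8.75, so genes with few counts had been removed before.

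The expected counts were rounded to whole numbers. The filterByExpr function of edgeR 4.0.16, with a minimum count of 10 and the group as design, kept 20604 genes. Library sizes were scaled by trimmed means of M values (TMM). Each gene was tested with edgeR's quasi-likelihood test in R 4.3.3 with the group as the only term, all 6 libraries in the fit and Benjamini-Hochberg adjustment over the genes tested. The threshold was an adjusted p of 0.05. Positive log2 fold changes mean higher in n-Braf. Levels are TMM-scaled CPM, the count divided by the scaled library size and set to a common total, given as mean ± SD over 3 libraries. The standard error of a log2 fold change is given as SE. Coordinates are those of GENCODE M21 on GRCm38, the assembly that mm10 names, matched through the gene identifiers.

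For gene groups, 45 lists of pathway genes and cell type markers, with 976 of their 1029 entries tested, were compared with the other genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. Adjustment was over the 45 lists. The test was repeated with the correlation estimated from the data, and with fry, which asks whether a list's genes move one way without comparing them with other genes. The design, the lists, the rule for naming genes and most alternatives were fixed before the data were examined. The rule named Braf and Camk2a, then genes past the threshold, and, because fewer than 10 passed, the genes with the smallest unadjusted p up to 10 names, given as values only. It also named up to 4 members of each list with the smallest unadjusted p. Unnamed gene models were counted but not named. Some genes that the rule selects are not reported here.

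The alternatives were other scalings (relative log expression, upper quartile, library size alone), DESeq2 1.42.0, edgeR's exact test, limma-voom, no filter or a mean CPM of at least 1, a replicate block, age as a covariate, leaving out each library in turn, leaving out mitochondrial and the 20 most abundant genes, and an adjusted p of 0.1. Added after the data were seen were robust quasi-likelihood, quasi-likelihood without legacy settings, edgeR's likelihood ratio test, the mean log2 CPM of the choroid plexus, the myelin or the neocortex list as a covariate, leaving out controls 1 and 2 together, where control 3 alone is assumed to vary like the n-Braf libraries, and leaving out ribosomal and 7S RNA genes.

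The gene test was run on simulated data for this comparison, with counts drawn for 20604 genes of which 200 were changed. It recovered 34% of the genes changed by a fold of 1.5, 62% at a fold of 2, 92% at a fold of 4 and 96% at a fold of 8, with 17 unchanged genes called. With no change simulated it called 1 gene, and camera called 0 lists. The simulated genes varied independently, while in the real data the estimated correlation within a list reached 0.94, for the choroid plexus markers. The 0 lists therefore do not show how often camera calls lists whose genes vary together. The exact test called 45 unchanged genes in the same simulation.

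Every pair of libraries differed by more than counting noise, with a chi-square per degree of freedom over genes of 51.0 to 69.1 in the 5 pairs that include control 1 and of 8.88 to 14.1 in the others, so no library was counted as a copy of another. Assigned counts per library lay between 25227112 and 31832245. Intervals on shares of counts are exact Clopper-Pearson intervals at 95% and cover counting error only, since the reads carried no molecular identifiers that were used here.

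For the closing observations, a list's median log2 fold change was set against 10000 random lists, each member replaced by one of the 100 genes nearest to it in rank of mean log2 CPM, length and GC content of the longest GENCODE M21 transcript. Medians of lists were compared by a two-sided permutation test with 100000 resamples. Group differences of a list's mean log2 CPM per library came from a linear model with and without a score covariate. The 10 ways to part the 6 libraries into 3 and 3 were each tested like the real groups.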

Results

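Hippocampal transcriptomes were compared between 2 groups of adult male mice that carry 1 Braf allele with the Q241R substitution. BRAF is a kinase of the RAS-ERK signalling pathway, and the series title names this substitution in a model of cardio-facio-cutaneous syndrome, a developmental disorder. In the 3 control mice the mutant allele was unrecombined and kept its Neo cassette, as the genotype label gives it. In the 3 n-Braf mice a CaMKII-Cre transgene was present, and the design places expression of the mutant in mature excitatory neurons. The comparison addresses which hippocampal genes differ when the mutant is expressed in those neurons of the adult brain. The control mice were 31 to 32 weeks old and the n-Braf mice 32 to 34 weeks old. Wild-type hippocampus was not analysed here. The groups differ in the Cre transgene and in the Neo cassette together. Effects of either therefore cannot be told apart here from those of the mutant protein.

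The control libraries held 27608256, 25938650 and 25227112 assigned counts, and the n-Braf libraries 31832245, 31678125 and 30152839. The 2 mitochondrial ribosomal RNAs took 19.7% ± 0.675 of the counts in the controls and 20.1% ± 0.435 in n-Braf (SD, n = 3 each). Rn18s-rs5, a ribosomal RNA repeat, took 3.26% of the counts of control 1 (95% exact Clopper-Pearson interval 3.25 to 3.27) and between 0.534% and 0.782% in each of the other 5 libraries.

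Braf itself was higher in n-Braf, at 191 ± 12.1 CPM against 119 ± 4.18 CPM in the controls (SD, n = 3 each), a 1.61-fold difference (log2 fold change 0.69, SE 0.07). The gene (ENSMUSG00000002413) lies on chromosome 6 at 39603237 to 39725463, on the minus strand. The lowest n-Braf library had 184 CPM and the highest control library 123 CPM. The quasi-likelihood test of edgeR gave Braf, a gene named before the data were examined, an unadjusted p of 2.84e-06. Adjusted over all genes tested, the p was 0.0533, just outside the threshold. Camk2a, the source of the promoter used for Cre and a marker of excitatory neurons, had a log2 fold change of 0.16 (SE 0.11, adjusted p = 0.849).

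The genes with the next smallest p-values included several whose transcription is known to follow ERK activity, and each is given as a value because none passed the threshold. Etv5, an ETS transcription factor on chromosome 16 at 22381309 to 22439719, was at 65.0 ± 1.55 CPM in n-Braf and 42.0 ± 2.31 CPM in the controls, with an adjusted p of 0.0533. Dusp6, a phosphatase that removes phosphate from ERK, was at 36.1 ± 3.12 CPM against 20.5 ± 1.88 CPM, and Spred3, an inhibitor of the pathway, at 46.4 ± 3.65 CPM against 29.9 ± 2.04 CPM. Vgf, which encodes a secreted neuropeptide precursor induced by neurotrophins, was at 115 ± 13.3 CPM against 63.9 ± 8.45 CPM. Synj2, a phosphoinositide phosphatase, and Trib2, a pseudokinase, had log2 fold changes of 0.51 (SE 0.08) and 0.51 (SE 0.08). Lower in n-Braf were Oxr1, a gene of oxidation resistance on chromosome 15 at 41447482 to 41861048, at 145 ± 22.3 CPM against 256 ± 21.5 CPM, and Nek5, a kinase gene with few counts. Nek5 had 70, 46 and 23 counts in the control libraries and 4, 4 and 3 in the n-Braf libraries. In all of these genes except Camk2a the 3 n-Braf libraries lay on one side of the 3 controls. Over the controls Nek5 fell in the same order as the mean of the ependymal list described below (log2 deviations of 1.02, 0.67 and -0.038). The n-Braf libraries were lower than every control in both. Whether Nek5 and that list share a source was not tested.

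**Figure D1:**
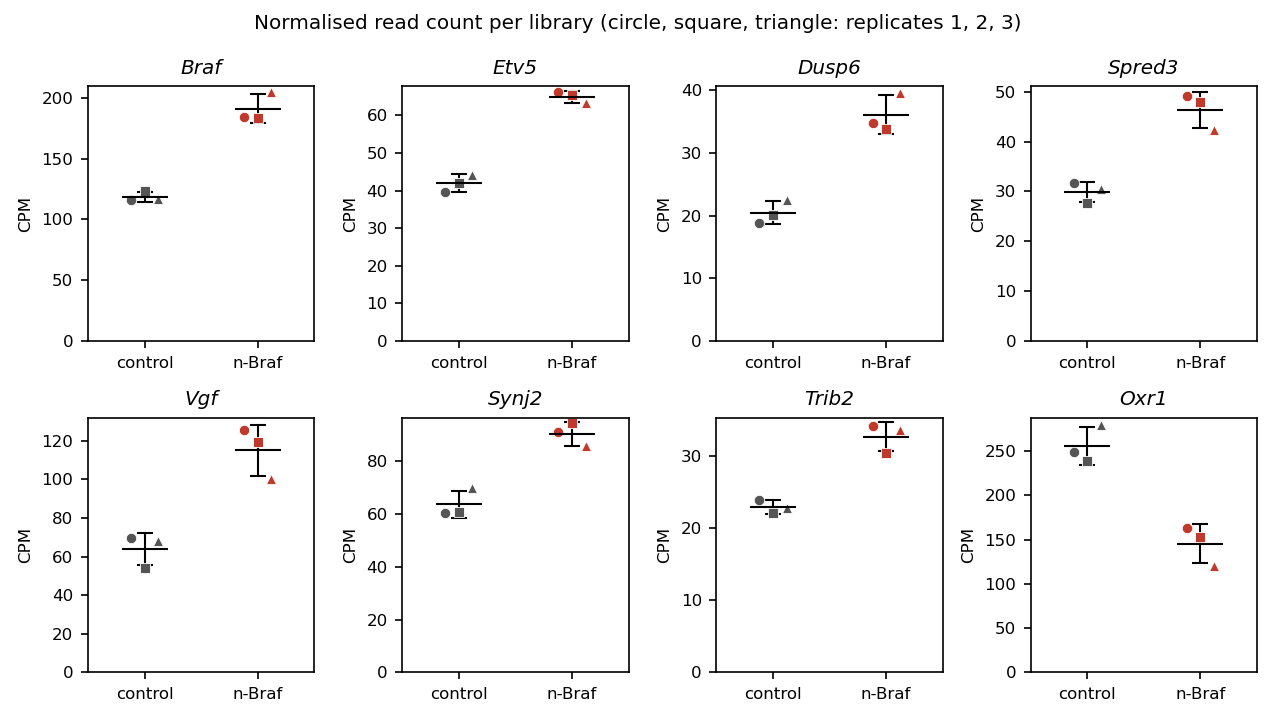
Normalised read count in CPM (vertical axes, from 0) of 8 genes in the 3 control and 3 n-Braf libraries, with points for single libraries and bars for the mean and SD. Braf is at 119 ± 4.18 CPM in the controls and 191 ± 12.1 CPM in n-Braf, Oxr1 is lower in n-Braf, and the groups do not overlap in any of the 8 genes.

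Over all 20604 genes, edgeR's quasi-likelihood test placed 0 genes higher and 0 lower in n-Braf at an adjusted p of 0.05. At an unadjusted p of 0.05 there were 1405 genes, 637 higher and 768 lower, where 1030 would fall by chance. The groups did not overlap in 2374 genes, 11.5% of those tested, and chance gives 10% for 3 against 3. Other tests on the same counts called more: DESeq2 called 29 higher and 50 lower, edgeR's exact test 15 and 51, its likelihood ratio test 15 and 56, and robust quasi-likelihood 4 and 1, while limma-voom called 0 and 0. The authors' deposited table has 29 genes with an adjusted p under 0.05, 14 higher and 15 lower, among them Braf, Nek5, Vgf, Etv5, Oxr1, Dusp6, Spred3, Synj2 and Trib2. All 29 had the same direction and did not overlap between groups here. Both comparisons used the same counts (Pearson r of the log2 fold changes across genes 0.99989), so this is not independent evidence. Without control 3 the quasi-likelihood test called 6 genes higher and 76 lower, and 19 of these 82 belong to the choroid plexus or ependymal lists. Those lists have 27 tested members, of which 0.107 would be called if the 82 calls fell evenly over all genes.

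The largest differences between the groups were in markers of the choroid plexus, the epithelium in the brain ventricles that secretes cerebrospinal fluid. All 16 tested markers were lower in n-Braf, with a median log2 fold change of -3.54, and the list fell (camera adjusted p = 6.87e-11; adjusted p = 0.614 with an estimated correlation). Over all genes 0 of the 16 passed, and adjusted over the list alone 16 did. The difference came from controls 1 and 2. Ttr, the thyroid hormone carrier transthyretin, was at 2036 CPM in control 1 and 1121 CPM in control 2, at 13.8 CPM in control 3, and at 3.32, 12.9 and 1.06 CPM in the n-Braf libraries. Folr1, a folate receptor, was at 20.1 and 12.1 CPM in controls 1 and 2 and at 0.428 CPM in control 3. Enpp2, the lysophospholipase autotaxin, and Lbp had log2 fold changes of -3.17 and -3.13. Leaving out controls 1 and 2 sets control 3 alone against the 3 n-Braf libraries, so in this fit, here and for other lists, the spread comes from n-Braf alone and the lone control is assumed to vary likewise. Against control 3 alone the choroid plexus list had a median of -0.23 (adjusted p = 0.104). Markers of ependymal cells, the ciliated cells that line the ventricles, fell too (11 of 11 lower, median log2 fold change -1.27, camera adjusted p = 2.86e-09; adjusted p = 0.42 with an estimated correlation). Adjusted over the list alone 10 passed, among them Dnah11 and Cfap44, genes of motile cilia, and Ccdc153 and Rarres2, and over all genes 0 did. The ependymal median was smaller against control 3 alone, at -0.34 (adjusted p = 0.00338). Over 27 alternatives the adjusted p ran from 2.35e-56 to 0.918 for the choroid plexus list and from 6.24e-21 to 0.42 for the ependymal list.

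**Figure D2:**
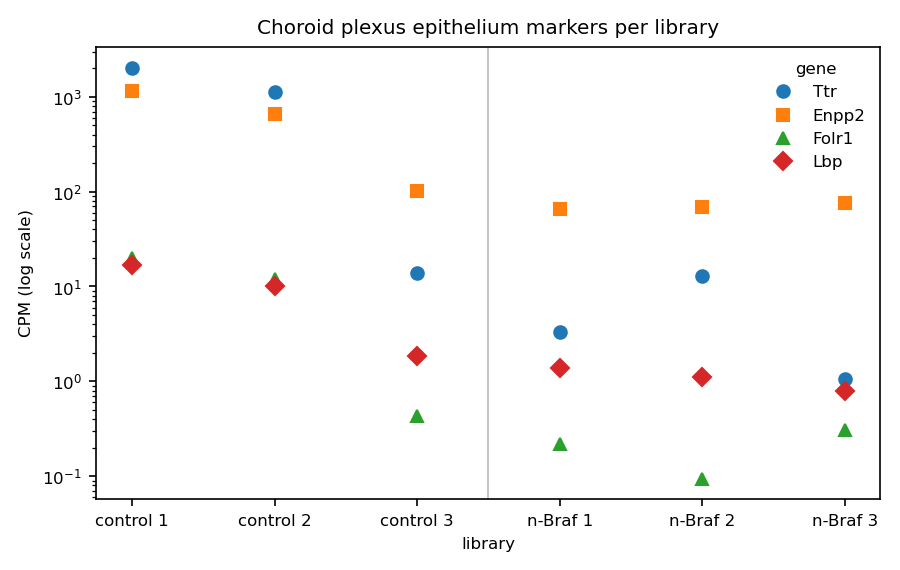
CPM on a log axis of 4 choroid plexus markers (symbols) in each of the 6 libraries (horizontal axis). Ttr is at 2036 and 1121 CPM in controls 1 and 2 and at 13.8 CPM or less in control 3 and the n-Braf libraries.

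Genes that ERK signalling induces, many of them its own negative regulators, rose as a group. Of 18 tested members 14 were higher and 4 lower, with a median log2 fold change of 0.21 (camera adjusted p = 4.88e-06; adjusted p = 0.122 with an estimated correlation; fry adjusted p = 0.0107). Adjusted over the list alone, 7 members rose and 0 fell, while over all genes 0 passed. The 7 were Etv5, Dusp6, Spred3 and Spred2, and, named after their values were seen, Spry4, Spred1 and Dusp4. Dusp6 had a log2 fold change of 0.82 (SE 0.10), Spry4 of 0.65 (SE 0.17) and Spred2, which binds RAF and blocks its activation, of 0.32 (SE 0.08). Lgals3bp, a secreted glycoprotein, went the other way at -0.65 (SE 0.25), with its highest level in control 1. The list's mean lay above the highest control in each of the 3 n-Braf libraries. Against control 3 alone, a single library, it had a median of 0.23 and an adjusted p of 0.00204, within a range over 27 alternatives of 1.59e-15 to 0.122. The broader list of RAS-ERK pathway components had a median of 0.04, with 27 of 43 members higher (camera adjusted p = 0.0336; adjusted p = 0.637 with an estimated correlation). In it 4 members rose when adjusted over the list alone: Braf, the adaptor Shc3 (log2 fold change 0.49, SE 0.10), the striatum-enriched phosphatase Ptpn5 (0.36, SE 0.08) and the kinase Rps6ka3 (0.29, SE 0.07). Over all genes 0 of the 43 passed. This list lost its call without control 1 (adjusted p = 0.301, median 0.013), control 2 (0.0721, median 0.048), n-Braf 2 (0.0958, median 0.042) or n-Braf 3 (0.163, median 0.017), with age as a covariate (0.0624, median 0.04), with library sizes alone as the scaling (0.0634, median 0.02), and against control 3 alone (0.815, median 0.02), within a range over its alternatives of 0.000114 to 0.952.

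**Figure D3:**
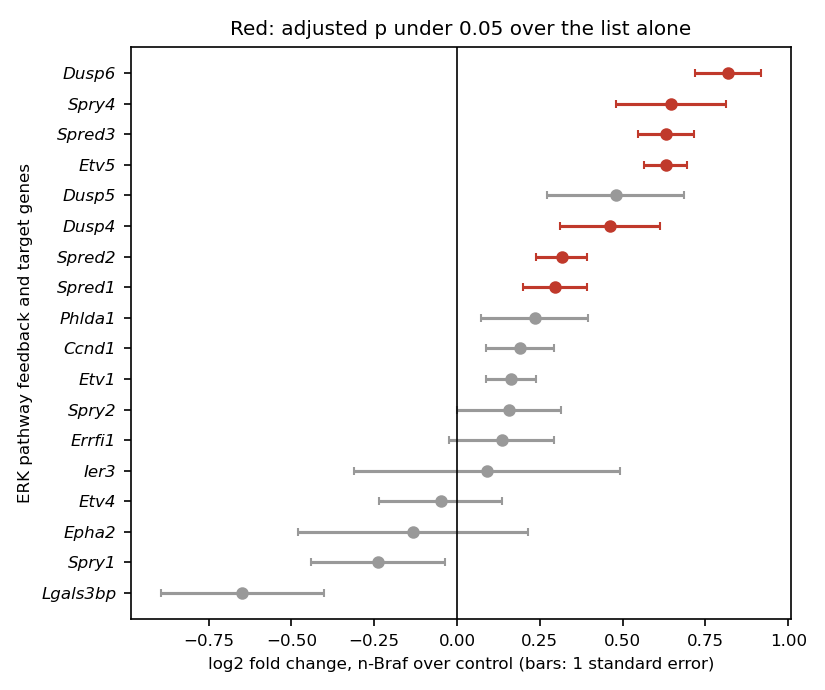
Log2 fold change of n-Braf over control (horizontal axis; bars are 1 SE) of the 18 tested ERK feedback and target genes. The 7 genes in red have an adjusted p under 0.05 over the list alone and are all higher in n-Braf, and Lgals3bp is lowest at -0.65.

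Lists of ion channels and of the synapse rose by small amounts, and in the 4 lists of this paragraph 0 members passed over all genes or adjusted over the list alone. Among potassium and HCN channels, which set the resting potential and firing of neurons, 40 of 45 were higher (median log2 fold change 0.11, camera adjusted p = 8.65e-06; adjusted p = 0.122 with an estimated correlation; fry adjusted p = 0.0332). Among its members Kcnip3 had a log2 fold change of 0.42 (SE 0.14) and Kcna2 of 0.21 (SE 0.07). Among genes of presynaptic release 34 of 40 were higher (median 0.12, camera adjusted p = 6.33e-05; adjusted p = 0.457 with an estimated correlation), with Syt12 at 0.33 (SE 0.09) and the active zone gene Bsn at 0.27 (SE 0.08). Sodium and calcium channels had 25 of 28 higher (median 0.13, camera adjusted p = 8.21e-05; adjusted p = 0.42 with an estimated correlation), with Cacng3 at 0.38 (SE 0.09) and Cacna1a at 0.25 (SE 0.08). Glutamate receptors had 20 of 25 higher (median 0.12, camera adjusted p = 0.00582; adjusted p = 0.457 with an estimated correlation), with the AMPA receptor subunit Gria3 at 0.29 (SE 0.09). The glutamate receptor list lost its call without control 1 (median 0.079, adjusted p = 0.0908) or n-Braf 1 (median 0.10, adjusted p = 0.0597). The presynaptic median was 0.074 without n-Braf 1 (adjusted p = 0.00749), and that of the sodium and calcium channels 0.084 without control 1 (adjusted p = 0.0179). Against control 3 alone, without the 2 libraries high in choroid plexus markers, the potassium channel list had a median of 0.09 (adjusted p = 0.0409), the presynaptic list 0.07 (adjusted p = 0.137), the sodium and calcium channel list 0.11 (adjusted p = 0.104) and the glutamate receptor list 0.10 (adjusted p = 0.243). Markers of the neighbouring neocortex moved with the presynaptic list in their mean log2 deviation from the average over the 6 libraries: n-Braf 1 was highest in both (0.52 for the markers, 0.12 for the list), and control 2 (-0.37 and -0.12) and n-Braf 3 (-0.38 and -0.049) were lowest in both. With the mean of the neocortical markers as a covariate the presynaptic list had a median of 0.08 (adjusted p = 0.00583). Over 27 alternatives the adjusted p ran from 1.81e-09 to 0.122, from 2.94e-08 to 0.457, from 7.86e-08 to 0.42 and from 4.71e-05 to 0.457 for these 4 lists in the same order.

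**Figure D4:**
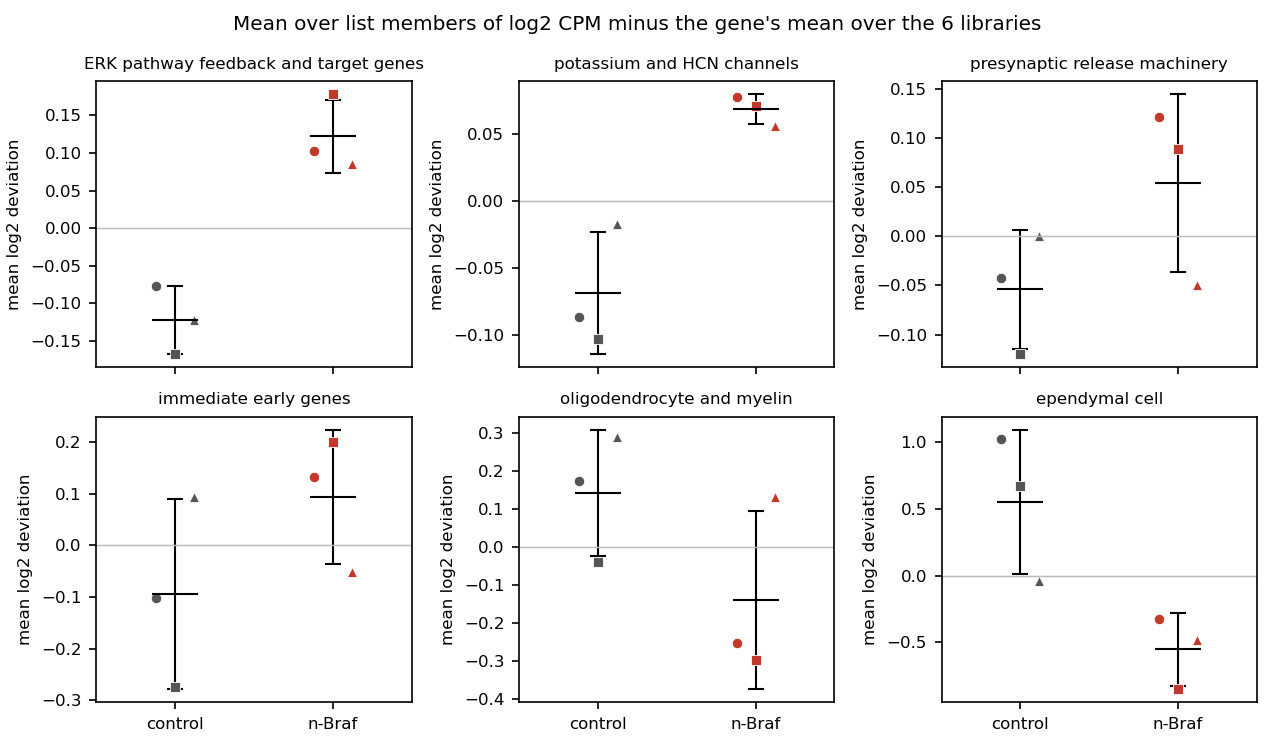
Mean over list members of log2 CPM minus each gene's mean over the 6 libraries (vertical axes) for 6 lists, with points for single libraries and bars for the mean and SD of 3. The groups do not overlap for the ERK, the potassium and HCN channel and the ependymal lists, and they overlap for the presynaptic, immediate early gene and myelin lists.

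Neuropeptides and secreted factors that neuronal activity induces rose (20 of 25 higher, median log2 fold change 0.16, camera adjusted p = 0.00458; adjusted p = 0.264 with an estimated correlation; fry adjusted p = 0.0332). Vgf and Nptx2, a pentraxin of excitatory synapses (log2 fold change 0.60, SE 0.13), rose when adjusted over the list alone, and over all genes 0 did. Npy was at 0.58 (SE 0.18) and Bdnf, a neurotrophin, at 0.35 (SE 0.12). Immediate early genes, transcribed within minutes of neuronal stimulation, had 18 of 25 higher (median 0.19, camera adjusted p = 0.000761; adjusted p = 0.637 with an estimated correlation). Of these Egr3 rose when adjusted over the list alone (log2 fold change 0.36, SE 0.07), over all genes 0 did, and Egr1 was at 0.47 (SE 0.14) and Fosb at 0.52 (SE 0.16). Without control 2 the immediate early list had a median of 0.089 (adjusted p = 0.0528) and without control 3 of 0.29 (adjusted p = 5.92e-06). With the mean of the neocortical markers as a covariate this list had a median of 0.11 (camera adjusted p = 0.0412). Against control 3 alone its median was 0.02 (adjusted p = 0.815), and with the mean of the choroid plexus markers as a covariate it was -0.0052 (adjusted p = 0.836, with the test's direction upward). The neuropeptide list, against control 3 alone, had a median of 0.19 and an adjusted p of 0.104, and without control 1 a median of 0.26 (adjusted p = 0.00388). Markers of CA1 pyramidal neurons had 11 of 12 higher (median 0.22, camera adjusted p = 0.00358; adjusted p = 0.264 with an estimated correlation), and Ndst3, a heparan sulfate sulfotransferase gene, rose when adjusted over the list alone (0.29, SE 0.06) and not over all genes. Dcn, which encodes the proteoglycan decorin and is also on the leptomeningeal list, was at -0.70 (SE 0.27), with the 3 n-Braf libraries below the 3 controls. The CA1 list had a median of 0.25 and an adjusted p of 0.158 against control 3 alone. With age as a covariate its median was 0.097 (adjusted p = 0.115), and without n-Braf 3 it was 0.11 (adjusted p = 0.0493). Over 27 alternatives the adjusted p ran from 9.46e-07 to 0.264 for the neuropeptide list, from 4.69e-07 to 0.836 for the immediate early list and from 3.43e-06 to 0.264 for the CA1 list.

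Genes of oligodendrocytes and myelin fell, with 19 of 20 lower and a median log2 fold change of -0.29 (camera adjusted p = 4.48e-06; adjusted p = 0.637 with an estimated correlation). Over all genes 0 passed, and adjusted over the list alone 0 did. Trf, which encodes transferrin, was at -0.47 (SE 0.14), Fa2h, which hydroxylates myelin lipids, at -0.41 (SE 0.15), and Cnp at -0.29 (SE 0.11). The list's mean overlapped between the groups, since n-Braf 3 lay above control 2. The median was -0.19 without control 3 (adjusted p = 0.00831) and -0.45 without n-Braf 3 (adjusted p = 1.75e-11). Against control 3 alone, the library with the highest mean of this list, its median was -0.43 (adjusted p = 1.86e-07), within a range over 27 alternatives of 5.01e-12 to 0.878.

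The other 7 lists that passed had camera adjusted p-values between 0.0122 and 0.0494, and between 0.637 and 0.735 with an estimated correlation. The 13 protein genes of the mitochondrial genome had a median log2 fold change of 0.15 (12 higher), with mt-Nd5 at 0.19 (SE 0.08). Their list lost its call without control 2 (median 0.14, adjusted p = 0.0631), control 3 (0.13, adjusted p = 0.215) or n-Braf 3 (0.083, adjusted p = 0.109), and with age as a covariate, where the median was 0.044 (adjusted p = 0.915). Control 3 had the lowest mean of this list, and against it alone the median was 0.18 (adjusted p = 0.0027). Glucocorticoid-responsive genes had 16 of 18 higher (median 0.15), with Mt2 at 0.47 (SE 0.17) and Pdk4 at -0.29 (SE 0.13), neocortical markers 13 of 14 (median 0.18), with Hs3st2 at 0.56 (SE 0.21), and GABA receptors 12 of 15 (median 0.10), with Gabra5 at 0.34 (SE 0.11). Monoamine, acetylcholine and opioid receptors had 28 of 37 higher (median 0.08). In that list the serotonin receptor gene Htr5b rose when adjusted over the list alone (log2 fold change 0.95, SE 0.19) and Htr2c, which is also abundant in choroid plexus, was at -0.75 (SE 0.30). Interferon and antigen presentation genes had 24 of 28 lower (median -0.18) and genes of disease-associated microglia 17 of 22 (median -0.21). Among the latter the tetraspanin gene Cd63 fell when adjusted over the list alone (-0.67, SE 0.15), while Ch25h, a cholesterol hydroxylase gene with 4 to 26 counts per library, was at 1.40 (SE 0.45). Over all genes 0 members of these 7 lists passed. Leaving out 1 library ended calls of each of the 7 lists, in part with smaller medians and in part with medians of about the same size. The glucocorticoid median was 0.071 without n-Braf 2 (adjusted p = 0.504), 0.089 without n-Braf 3 (0.395), 0.11 without control 1 (0.284) and 0.13 without control 2 (0.0865), and it was 0.28 without n-Braf 1 (4.83e-08). The neocortical median was 0.038 without n-Braf 1 (adjusted p = 0.353), but 0.17 without control 1 (0.12), 0.15 without control 2 (0.21) and 0.21 without n-Braf 2 (0.102), and it was 0.29 without control 3 (0.00439) and 0.31 without n-Braf 3 (7.24e-05). For the GABA receptors it was 0.044 without control 1 (adjusted p = 0.671), 0.073 without n-Braf 1 (0.105), 0.092 without n-Braf 2 (0.0615) and 0.097 without n-Braf 3 (0.17). The monoamine median was 0.032 without n-Braf 2 (adjusted p = 0.494), 0.062 without control 1 (0.21), 0.070 without n-Braf 1 (0.286) and 0.090 without control 3 (0.123), and it was 0.16 without n-Braf 3 (3.17e-05). The interferon median was -0.026 without control 1 (adjusted p = 0.981), -0.22 without control 3 (0.0583) and -0.17 without n-Braf 1 (0.0747), and it was -0.34 without control 2 (6e-07). For the disease-associated microglia genes it was -0.10 without control 1 (adjusted p = 0.286) or control 3 (0.161) and -0.12 without n-Braf 2 (0.379). Over all alternatives the adjusted p of the 7 lists ran from 4.83e-08 to 0.981. With age as a covariate the interferon (median -0.20, adjusted p = 0.0972) and GABA receptor (median 0.067, adjusted p = 0.161) lists did not pass. Against control 3 alone the interferon list had a median of -0.15 (adjusted p = 0.0355), and 5 of the 7 did not pass. Among these the median was smaller for the glucocorticoid (0.05, adjusted p = 0.939) and neocortical (0.06, adjusted p = 0.955) lists and below 0 for the GABA receptors (-0.03, adjusted p = 0.815, with the test's direction upward), while it was 0.10 for the monoamine (adjusted p = 0.104) and -0.19 for the disease-associated microglia list (adjusted p = 0.104).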

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

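Age as a covariate, other scalings, other tests, filters, the replicate block, leaving out each library, and the list tests with an estimated correlation or fry were chosen before the data were examined. The robust, non-legacy and likelihood ratio tests, the choroid plexus, myelin and neocortex score covariates, leaving out controls 1 and 2 together, and leaving out ribosomal and 7S RNA genes were chosen after. Against 0 higher and 0 lower genes, DESeq2 gave 29 and 50, the exact test 15 and 51, the likelihood ratio test 15 and 56, robust quasi-likelihood 4 and 1, non-legacy quasi-likelihood 1 and 0, leaving out mitochondrial and the 20 most abundant genes 1 and 0, leaving out ribosomal and 7S RNA genes 1 and 0, leaving out controls 1 and 2 together 2 and 1, the neocortex score as a covariate 1 and 1, and an adjusted p of 0.1 gave 2 and 0. Leaving out 1 library gave 0 to 6 higher and 0 to 76 lower genes, the highest without control 3. The Braf log2 fold change passed the threshold at 0.69 with DESeq2, the exact, likelihood ratio, robust and non-legacy tests, at 0.69 without mitochondrial and abundant genes or without ribosomal and 7S RNA genes, at 0.73 with the neocortex score as a covariate and at 0.68 without control 3; leaving out 1 library gave 0.63 to 0.72. The cause of these differences in calls was not tested.

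Of the 45 lists, 19 passed with the preset correlation, 0 with an estimated correlation, 3 with fry, 6 with the choroid plexus covariate and 8 without controls 1 and 2, a fit that rests on 1 control library. Leaving out 1 library gave 11 to 17, the lowest without control 1. The ERK list passed under 26 of 27 alternatives, with adjusted p-values from 1.59e-15 to 0.122, and the potassium channel list under 25. With the choroid plexus covariate the direction of the choroid plexus list (adjusted p = 0.918) and of the GABA receptor list (0.918) turned, as did the log2 fold changes of Lgals3bp (0.067), Htr2c (0.26) and Tafa2 (-0.0127), and the medians of the immediate early (-0.0052), neocortical (-0.028) and RAS-ERK component (-0.0048) lists fell below 0 while their tests stayed upward. Without controls 1 and 2 those of Htr2c (0.13) and Tafa2 (-0.0201) turned. With the myelin covariate the myelin (0.878), monoamine (0.539) and disease-associated microglia (0.891) lists turned, and with age as a covariate Camk2a did (-0.10). The myelin covariate also ended the calls of the interferon (0.76), neocortical (0.475), glutamate receptor (0.137) and GABA receptor (0.0768) lists. Age as a covariate, the n-Braf mice being older on average, ended the calls of the mitochondrial (0.915), CA1 (0.115), GABA receptor (0.161), interferon (0.0972) and RAS-ERK component (0.0624) lists, and library sizes alone those of the RAS-ERK component (0.0634), GABA receptor (0.0854) and disease-associated microglia (0.0516) lists. With the neocortex score as a covariate the neocortical (0.864), monoamine (0.232), disease-associated microglia (0.0922) and GABA receptor (0.0828) lists did not pass. A score covariate removes its own list by construction; the cause of the other changes was not tested.

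A replicate block was fitted although the numbers did not pair the mice: the deviations of same-numbered libraries from their group means correlated at 0.103, -0.05 and -0.01 across genes, and not every library correlated best with its own number. With the replicate block 0 genes were higher, 0 were lower, the Braf log2 fold change was 0.69, and 17 lists passed. The calls it ended were those of the RAS-ERK components (0.0544, median 0.05), the disease-associated microglia genes (0.081, median -0.19) and the GABA receptors (0.081, median 0.10). With 3 mice per group and 25227112 counts or more per library, the simulation recovered 34% of genes changed by a fold of 1.5, so differences of that size were often not detectable here.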

Other observations

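Markers of most resident cell types did not pass the list test. The 26 lists that did not pass had camera adjusted p-values from 0.0694 to 0.949. Dentate granule neuron markers had a median log2 fold change of -0.12 (18 of 22 lower, adjusted p = 0.182; -0.28 with adjusted p = 4.5e-07 without n-Braf 3 and -0.38 with adjusted p = 5.39e-07 with age as a covariate, within a range over 27 alternatives of 4.5e-07 to 0.989), pan-excitatory neuron markers 0.12 (10 of 12 higher, adjusted p = 0.138), GABAergic interneuron markers 0.04 (adjusted p = 0.284) and microglia markers 0.00 (adjusted p = 0.774). The microglia list passed in opposite directions elsewhere: its median was -0.27 with the choroid plexus score as a covariate (adjusted p = 0.000435), -0.21 (adjusted p = 0.0212) against control 3 alone, a single library and the highest of the 6 in this list, -0.18 with age as a covariate (adjusted p = 0.0249), 0.18 with the myelin score as a covariate (adjusted p = 0.0133) and 0.12 without n-Braf 2 (adjusted p = 0.0223), within a range over 27 alternatives of 0.000435 to 0.963. The mean of the dentate granule list per library lay at -0.22 and -0.26 in n-Braf 1 and 2, at 0.30 in n-Braf 3 and at 0.053, 0.15 and -0.018 in the controls, as log2 deviations from the average of the 6. The leptomeningeal, CA2, pan-excitatory, reactive astrocyte, dentate granule, subiculum, nuclear respiratory chain and interneuron lists passed under 9, 6, 5, 3, 2, 2, 2 and 1 of the 27 alternatives. Among these were fits without 1 library: control 2 or n-Braf 1 for the leptomeningeal (medians -0.76 and -0.82) and reactive astrocyte lists (-0.23 and -0.34), control 3 for CA2 (-0.19) and subiculum (0.12), n-Braf 3 for CA2 (-0.30) and n-Braf 2 for the pan-excitatory list (0.13). Leptomeningeal fibroblast markers had the lowest adjusted p of these lists, with 13 of 15 lower (median -0.37). The CA2 list, whose marker Sostdc1 is also on the choroid plexus list, had its highest means in controls 1 and 2 (log2 deviations 0.57 and 0.38). The CA2 median was -0.060 with the choroid plexus score as a covariate and -0.016 against control 3 alone. In 9 of the 26 lists the median, the mean and the test differed in sign, among them astrocytes (median 0.02, mean -0.02), mossy cells (median -0.14, mean 0.00) and oligodendrocyte precursors (median 0.07, mean -0.04). Oligodendrocyte precursor markers passed fry's test for change in either direction (adjusted p = 0.0336).

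Oxr1 had 6 tested neighbours within 1 Mb on chromosome 15, with a median log2 fold change of 0.09 against its own -0.82.

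The tests in the next paragraphs that were chosen after the result was seen are those of choroid plexus tissue, myelin, neocortex tissue and excitatory neuron RNA; those of gene properties and of other splits were set before.

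The ERK feedback and target list was higher in n-Braf, with a median log2 fold change of 0.21. With the choroid plexus score as a covariate the median was 0.26 (camera adjusted p = 0.000435, within a range over 27 alternatives of 1.59e-15 to 0.122). The list's mean per library then differed by 0.26 (95% interval 0.06 to 0.47), against 0.24 (0.14 to 0.35) without the score. That score was high only in controls 1 and 2 (mean log2 deviations 3.34 and 2.47), against -1.23 in control 3 and -1.69 to -1.23 in n-Braf. The fit therefore rests largely on control 3, 1 library, and choroid plexus tissue in controls 1 and 2 stays open as a cause. The expression level, length and GC content of the 18 genes are argued against as the cause, since the median lay at percentile 100 of 10000 matched random lists, whose median was 0.00. More excitatory neuron RNA in n-Braf stays open: the ERK median exceeded that of 12 pan-excitatory markers by 0.10, with a two-sided permutation p of 0.0957 over genes, which are not independent replicates. Expression of mutant Braf, which the design names, stays open and was not tested apart from these, since each library with Cre also has more Braf RNA. Nor can it be told apart from Cre itself or from the loss of the Neo cassette.

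The choroid plexus list was lower in n-Braf because of controls 1 and 2, which lay above the n-Braf mean by a median of 4.43 and 3.61 on the log2 scale, while control 3 lay 0.24 above it. Choroid plexus tissue taken along with the hippocampus in those 2 dissections is a candidate source. The log2 ratio of control 1 to control 2 had an SD of 0.25 over the 16 markers around a median of 0.87. Such an even ratio would follow from any source that puts the same tissue in both controls. It uses no value of control 3 or n-Braf, so it does not tell such sources apart. Of the 16 markers 9 had a mean above 1 CPM in n-Braf as well and 1 is also on another list. An effect of genotype on the choroid plexus was not tested, and 1 control library without the signal excludes nothing.

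The 4 channel and synapse lists were higher in n-Braf, with a median log2 fold change of 0.12 over 138 genes, and expression level, length and GC content are argued against, since that median lay at percentile 100 of 10000 matched random lists, whose median was 0.04. For the potassium channel list, less myelin in n-Braf is argued against as the whole cause. The difference of its mean per library was 0.14 (95% interval 0.06 to 0.21), and 0.151 (0.03 to 0.28) with the myelin score as a covariate. With the choroid plexus score the difference was 0.0847 (0.02 to 0.15), and the list's camera call ended (adjusted p = 0.105, median 0.09 against 0.11). That fit, too, rests largely on control 3 as the only control low in the score, so choroid plexus tissue in the controls stays open for this list. For the presynaptic list, more neocortex tissue in n-Braf stays open. With the neocortex score as a covariate the list's difference was 0.0625 (0.01 to 0.11), against 0.11 (-0.07 to 0.28) without it. The list's camera adjusted p with the score was 0.00583. The score is a mean of 14 markers and may follow tissue content only in part. Some difference can then remain even if tissue is the whole cause. With the neocortex score the difference was 0.124 (0.05 to 0.20) for the potassium channels. It was 0.119 (-0.03 to 0.27) for the sodium and calcium channels and 0.0726 (-0.01 to 0.16) for the glutamate receptors. Both of the latter intervals include 0, so more neocortex tissue stays open for those lists as well. For the 3 lists other than potassium channels together, choroid plexus tissue and less myelin cannot be told apart from an effect of genotype: the difference of 0.10 (0.02 to 0.19) was 0.0604 (-0.07 to 0.19) with the choroid plexus score, where 0 of the 3 passed camera, and 0.0868 (-0.06 to 0.23) with the myelin score, where the presynaptic (adjusted p = 0.016, median 0.07) and the sodium and calcium channel lists (0.00222, median 0.13) passed, but with 3 residual degrees of freedom both intervals include 0. An earlier bound of 2 standard errors, which the difference over all 4 lists exceeded with either score (0.068, SE 0.03, and 0.11, SE 0.04), was replaced by these intervals after the values were seen, because so few degrees of freedom make it too lenient, and the lists were parted after that.

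The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 0 genes past the adjusted threshold and the highest other gave 1; no split can give fewer than 0, so this comparison decides nothing. At an unadjusted p of 0.05 the real split gave 1405 genes and the highest other 1455, so 2 of the 10 splits gave as many; that other split set control 1 with n-Braf 1 and n-Braf 2. For lists past the threshold the real split gave 19 and the others between 2 and 14, so camera with the preset correlation called lists in every split. For the size of the ERK list's mean log2 fold change it gave 0.23 and the highest other 0.15, and in both of these 1 of the 10 splits, the real one, gave as much.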
